A study of Mus musculus with 12 samples.

How the data were processed

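Gene expression was measured in mouse CD8 T cells on 12 Affymetrix arrays, 3 in each of 4 groups: Tc1 and Tc17 cells, each from wild-type (WT) mice and from mice whose T cells lacked STAT3 (STAT3-/-, made with a Cd4-driven Cre recombinase and a floxed allele of the gene). Per the labels, naive CD8 T cells from spleen of both genotypes were mixed in equal numbers before activation with anti-CD3 at 1 µg/ml and anti-CD28 at 3 µg/ml. Cells were cultured for 4 days in all, 3 days with IL-12 for Tc1 or with IL-6 and TGF-beta for Tc17 and 1 more day with IL-2, and the genotypes were then sorted apart by allelic surface markers. Total RNA was purified on columns and labelled with biotin.

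The deposited values are on a log2 scale, with 1 value per probe set and array. The authors made them with RMA, which corrects background, normalizes between arrays and summarises probes, and with Partek, per the submitters' processing notes. Which step each tool did, and their versions, are not given in the sources used here. The log2 scale was read from the values, which reached 13.3 with array medians from 3.95 to 4.10. RMA narrows differences near background, so fold changes of dim genes are understated. For arrays the number of samples, 2 biological samples per group, limits the precision.

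Of 41345 probe sets, 23521 had exactly 1 gene symbol in the platform annotation, 1814 had several and 16010 had none as used here. Only those with 1 symbol were used for named genes. Entrez identifiers of 23328 of them matched a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for names and for which genes neighbour each other. Where a gene had more than 1 probe set, as 1082 genes did, the one with the highest mean was kept, giving 22180 genes. Genes were tested if at least 1 group mean reached 5 on the log2 scale. This left 9862 genes and removed 12318.

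Each group's labels name biological replicates 1 and 2 and a technical replicate 2. The technical array was averaged with biological replicate 2, whose number it shares, so that each group had 2 samples. It was also read as belonging to replicate 1, left out, or kept as a sample of its own. No array columns were identical. The SD of the differences over tested genes was 0.144 to 0.192 between biological arrays 1 and 2 of a group, and 0.209 to 0.352 between biological array 2 and the technical array. The labels do not say which biological sample the technical array repeats, and as it differed more from the biological arrays than these did from each other, it may come from another batch or culture. The second sample of a group, and the spread between its samples, would then include that difference. The labels do not say which animals or cultures the replicates came from, so p-values measure only the spread between these samples, which may be partly technical.

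Group means over all 8 samples were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend or robust options), with 4 residual degrees of freedom and 4.87 prior ones. Tables were handled in R with the data.table package (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 5 contrasts were STAT3-/- over WT in Tc17, the same in Tc1, the difference between them (the interaction), and Tc17 over Tc1 within each genotype. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All adjusted p-values of single genes are from limma and two-sided.

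A set of 24 gene lists was fixed before the data were examined: type 17 program, type 1 program, cytotoxic granule and NK receptor, STAT3 target, interferon-stimulated, IL-2 and STAT5 target, TGF-beta response, naive and memory, inhibitory receptor and exhaustion, regulatory T cell, type 2 program, cell cycle, glycolysis and hypoxia, cholesterol synthesis, BCL2 family and death receptor, homing receptor, cytokine receptor, stress and immediate early, CD8 T cell identity, and markers of CD4 T cells, B cells, myeloid cells, NK and innate-like T cells and erythroid cells. Some genes stand on several lists. Lists with at least 3 tested members were tested against all other genes with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. The estimate lay below the preset for the type 17 (-0.0443), type 1 (-0.0099), homing receptor (-0.0398), type 2 (-0.0832) and IL-2 and STAT5 target (-0.0250) lists. A higher p in the second test of these lists does not come from correlation among their members. For STAT3-/- over WT in Tc17 the unadjusted camera p rose from 1.1e-20 to 0.00060 for type 17. It rose from 0.0038 to 0.0365 for type 1. A call lost in the second test by any other list therefore cannot be put down to correlation among its members alone. Counts of called members are given over all genes and adjusted over the list alone.

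The genes named were fixed by rule before the data were examined. They were Stat3, then per contrast the 10 largest rises and 10 largest falls among called genes (5 and 5 for the interaction and for Tc17 over Tc1 in STAT3-/-), up to 4 called members of each list with the largest changes or up to 2 uncalled ones where none was called, and always Il17a, Il17f, Il23r, Ifng, Tbx21, Eomes, Gzmb, Prf1 and Socs3. Predicted genes, receptor gene segments, olfactory receptors and small RNAs were passed over. Some genes of the rule and of the lists are not reported here.

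The fit was tested on simulated data for the Tc17 genotype comparison, with 9862 genes, 20 simulations and 200 changed genes. It recovered 83.9% of genes changed 1.5-fold, 99.2% of those changed 2-fold and 100% of those changed 4-fold, with a mean of 13.1 false calls, 6.49% of calls. With 20 simulated lists of 15 genes shifted by 0.5, camera called 20, and it called 1 of 380 lists with no shift. The simulated genes were independent of each other, so these runs do not show how camera behaves on lists whose members correlate. Among the real lists the estimated correlation was as high as 0.313, for cholesterol synthesis.

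Alternatives planned in advance covered the technical arrays, the replicate number as a block, the groups in the fit, the dim filter, the variance model, the scaling of arrays, the choice of probe set, the threshold and leaving out each sample. The alternatives added after seeing the data were leaving out the Tc17 WT technical array, subtracting each array's median over tested genes, averaging the biological arrays as 1 sample beside the technical one, and using 1 Tc17 WT sample in each comparison of an overlap.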

Results

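Expression was profiled in CD8 T cells activated for 3 days under IL-12, which drives a cytotoxic type 1 (Tc1) fate, or under IL-6 and TGF-beta, which drive an IL-17-producing (Tc17) fate. A further day of culture with IL-2 followed. STAT3 is the transcription factor through which the IL-6 receptor signals. WT and STAT3-/- cells had been cultured together and were sorted apart, giving 4 groups of 2 samples made from 12 arrays. Array medians lay between 3.95 and 4.10 on the log2 scale. The Tc17 WT technical array stood apart: its median correlation with the other arrays was 0.971, against at least 0.984 for every other array, and it lay at 44.8 on the first principal component (54.4% of the variance), where the other Tc17 WT arrays lay at 25.4 and 25.8.

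Stat3 itself was low in every STAT3-/- array. Its log2 value was 9.77 to 10.13 on Tc1 WT arrays, 6.99 to 7.67 on Tc1 STAT3-/- arrays, 10.38 to 10.72 on Tc17 WT arrays and 7.59 to 7.93 on Tc17 STAT3-/- arrays. It fell by 2.85 ± 0.18 (SE) in Tc17 (adjusted p = 1.4e-05) and by 2.66 ± 0.18 in Tc1 (adjusted p = 0.00029), with n = 2 samples per group. The annotation does not say which exons the probes cover, and probes outside the deleted part would check nothing, so the signal left in STAT3-/- cells has no reading here.

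**Figure D1:**
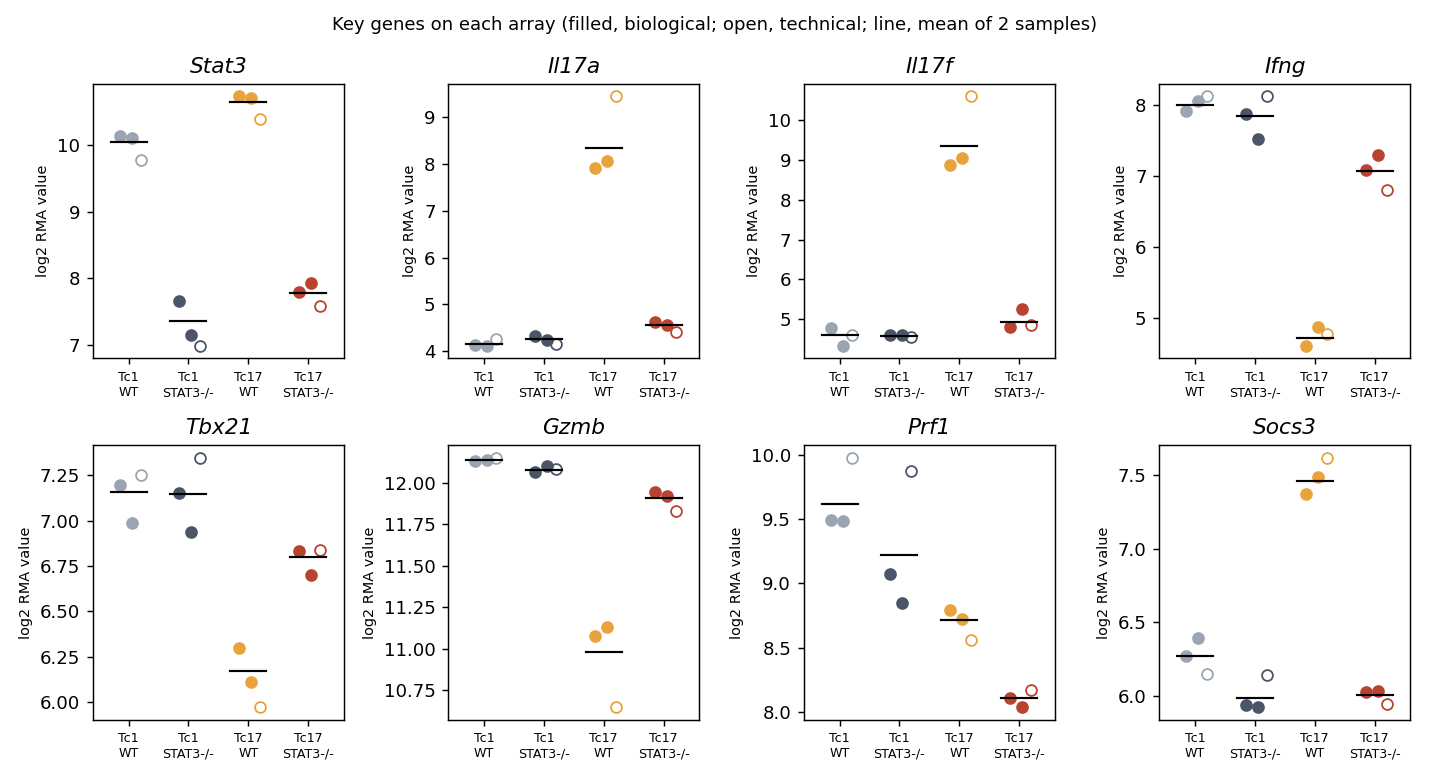
Log2 RMA value of 8 genes on each of the 12 arrays, by group, with filled points for biological arrays, open points for technical arrays and a line at the mean of the 2 samples. Il17a and Il17f stood high only in Tc17 WT, Stat3 was lower in both STAT3-/- groups, and Ifng and Gzmb were lower in Tc17 WT than in the other groups.

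The series title asks how STAT3 shapes Tc17 cells, which the comparison of the genotypes in Tc17 addresses. Without STAT3, Tc17 cells had far less RNA of the cytokines that define them. Il17f fell by 4.43 ± 0.26 on the log2 scale, from 9.35 ± 0.67 (SD, n = 2) to 4.92 ± 0.17, and Il17a fell by 3.77 ± 0.22, from 8.33 ± 0.60 to 4.56 ± 0.10, both ending near background, where RMA understates differences. The SDs in Tc17 WT were widened by the technical array. Il17f was 10.61 on it, against 8.88 and 9.05 on the biological arrays, and Il17a 9.44, against 7.90 and 8.07. Il21, an autocrine cytokine of type 17 cells, fell by 2.88, Il24, an IL-10 family cytokine, by 4.17, and Maf, a transcription factor of type 17 cells, by 3.21. In the opposite direction Ifng, the main type 1 cytokine, rose by 2.35 ± 0.11, from 4.72 ± 0.15 to 7.07 ± 0.03. Adjusted p-values of these 6 genes were at most 1.2e-05.

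Of 9862 genes tested, 2473 differed in Tc17, 1799 higher and 674 lower in STAT3-/- cells, and 3859 had an unadjusted p under 0.05. Changes of at least 2-fold were more even, with 144 higher and 161 lower. Other large falls were Cysltr1, a leukotriene receptor (-3.74), Ctse, the protease cathepsin E (-3.23), Ecm1, an extracellular matrix protein (-3.19), Tgm2, a transglutaminase (-3.17), Igfbp4, a binding protein of insulin-like growth factors (-3.12), and Anxa3, an annexin (-3.08). Large rises were Clnk, a signalling adaptor (2.95), Mid1, a ubiquitin ligase (2.85), Itih5 (2.73), Mndal, an interferon-inducible gene (2.70), Xcl1, a chemokine of activated CD8 T cells (2.69), Ccl5, another chemokine (2.59), Tmem273 (2.50), Pygm, the muscle form of glycogen phosphorylase (2.25), and Ly6c2, a surface marker of effector and memory CD8 T cells (2.24).

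Of the 19 members of the type 17 program list 12 were tested. All 12 were lower in STAT3-/- Tc17 cells, over all genes and adjusted over the list alone (camera adjusted p = 2.0e-19). This call held with an estimated correlation (adjusted p = 0.0113), and the 12 members were lower under every scaling tried. Il17a and Il17f passed the dim filter only through Tc17 WT, which fixes the direction of their change. Hif1a, also on the list, was uncalled with the mean of its probe sets (limma adjusted p = 0.105). Il23r, which encodes the IL-23 receptor, was too dim to be tested and averaged 4.33 in Tc17 WT and 2.74 in Tc17 STAT3-/-. The Tc17 WT mean was pulled down by the technical array, at 3.09, against 4.56 and 5.12 on the biological arrays. Of 14 tested STAT3 targets, 9 were lower and 2 higher (9 and 3 adjusted over the list alone), with camera adjusted p = 4.5e-07 and adjusted p = 0.168 with an estimated correlation. Socs3, the feedback inhibitor of IL-6 signalling, fell by 1.46 ± 0.10, and Bcl3, a regulator of NF-kB, fell by 1.44 ± 0.12. Maf and Il21 are among the genes on both lists.

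The type 1 program moved the other way, with 8 of 15 members higher and 0 lower (9 higher and 1 lower adjusted over the list alone), camera adjusted p = 0.0144 and adjusted p = 0.173 with an estimated correlation. Fasl, the ligand of the death receptor Fas, rose by 1.94, Ccl3 by 1.22, and Tbx21, which encodes the type 1 regulator T-bet, by 0.63. Eomes, a related regulator, rose by 0.67 (adjusted p = 0.0174), a call lost without either Tc17 STAT3-/- sample (adjusted p = 0.120 and 0.0536) or without Tc17 WT replicate 2 (0.0962). Interferon-stimulated genes had 7 of 17 members higher and 0 lower (7 and 1 adjusted over the list alone), camera adjusted p = 0.0193 and adjusted p = 0.423 with an estimated correlation, and the list's call was lost without the Tc17 WT technical array. The guanylate-binding proteins Gbp7 (1.70), Gbp5 (1.33) and Gbp3 (1.25), which interferon-gamma induces, led it. Gbp7 was at 1.13 without Tc17 WT replicate 2.

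Cytotoxic genes split. Of 14 members, 4 were higher and 5 lower (6 and 5 adjusted over the list alone), and camera did not call the list (adjusted p = 0.162). Gzmb, encoding the killing protease granzyme B, rose by 0.93 ± 0.09, and Nkg7, a granule protein, by 1.00. Prf1, encoding the pore-forming protein perforin, fell by 0.61 ± 0.13, and the NK receptor genes Klrc1 and Klrd1, whose products pair, fell by 1.91 and 1.28. The Prf1 call (adjusted p = 0.0086) was lost without either Tc17 STAT3-/- sample (adjusted p = 0.0576 and 0.0589). Among inhibitory receptor and exhaustion genes 8 of 14 were higher and 3 lower, over all genes and over the list alone, with camera adjusted p = 0.0993. The inhibitory receptors Cd244a (1.63), Havcr2 (1.60) and Pdcd1 (1.24) rose, as did Prdm1, which encodes the effector regulator Blimp-1 (1.47).

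Cell-cycle genes were higher, 17 of 24 with 0 lower (21 and 0 adjusted over the list alone), camera adjusted p = 7.8e-06 and adjusted p = 0.173 with an estimated correlation. The replication helicase subunits Mcm5 and Mcm3 rose by 0.67 and 0.59, and the mitotic checkpoint kinase gene Bub1b by 0.58. Cholesterol synthesis genes had 9 of 15 members higher and 0 lower (11 and 0 adjusted over the list alone), camera adjusted p = 0.0011 and adjusted p = 0.402 with an estimated correlation. Dhcr7, the last enzyme of the pathway, rose by 0.92, and Hmgcs1, an early one, by 0.69. Both lists depended on scaling in number, not in direction: cell-cycle genes higher were 7 after subtracting each array's median of tested genes, 8 after cyclic loess, 13 after quantile normalization and 20 after subtracting the median of all probes, and cholesterol genes higher were 6, 6, 7 and 11.

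Naive and memory genes had 7 of 14 members lower and 4 higher, over all genes and over the list alone (camera adjusted p = 0.0193, and adjusted p = 0.423 with an estimated correlation). That call was lost with no dim filter (camera adjusted p = 0.132) and after subtracting the median of tested genes (0.0777). It was also lost with limma's fry, which does not compare a list with other genes (adjusted p = 0.0669). Fry called the other lists that camera called in Tc17, and also the inhibitory receptor (fry adjusted p = 0.0047) and BCL2 family (0.0032) lists. It cannot set a list apart from a shift of all tested genes. Satb1, a chromatin organiser of T cells, fell by 1.69, and S1pr1, the receptor for exit from lymph nodes, by 1.30. Of 12 homing receptors 5 were lower and 3 higher (6 and 4 adjusted over the list alone), with camera adjusted p = 0.0193 and adjusted p = 0.188 with an estimated correlation. Cxcr6 fell by 1.64 and Ccr4 by 1.33. The type 2 program list had 5 tested members, 3 lower and 2 higher by either adjustment (camera adjusted p = 0.0408, and adjusted p = 0.239 with an estimated correlation), and Il24 and Ccr4 led its falls. After subtracting the median of tested genes camera called neither homing receptors (adjusted p = 0.0880) nor the type 2 program (0.101). The homing and type 2 calls were lost without the Tc17 WT technical array or without Tc17 WT replicate 2 (adjusted p = 0.103 and 0.0905 without the latter), and the type 2 call also without Tc17 WT replicate 1 (0.0553) or either Tc1 STAT3-/- sample (0.0521).

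Camera called no other list in Tc17. Of 20 cytokine receptors 4 were higher and 6 lower (10 and 7 adjusted over the list alone, adjusted p = 0.138), with Il6ra, the IL-6 receptor chain, lower by a log2 change of -1.93 and Ifngr2, an interferon-gamma receptor chain, by -1.21. IL-2 and STAT5 targets had 3 higher and 4 lower of 14 by either adjustment (adjusted p = 0.162), TGF-beta response genes 2 higher and 1 lower of 13 (4 and 2 over the list alone, adjusted p = 0.737), and regulatory T cell genes 5 higher and 3 lower of 12 (5 and 4, adjusted p = 0.610). In the last list Ikzf2, encoding Helios, rose by 1.43, Lrrc32, which displays TGF-beta at the surface, by 0.92, and Foxp3, the lineage factor of regulatory T cells, by 1.00 (adjusted p = 0.0108). The Foxp3 call was lost without Tc17 STAT3-/- replicate 2 (adjusted p = 0.0799), and the change was 0.63 without Tc17 WT replicate 1. Glycolysis and hypoxia genes had 1 higher and 3 lower of 14 by either adjustment (adjusted p = 0.230), and Hif1a, the hypoxia factor, fell by 0.89, or by 0.36 and uncalled with the mean of its probe sets. BCL2 family and death receptor genes had 4 higher and 1 lower of 11 by either adjustment (adjusted p = 0.275), and Bcl2l11, encoding the death-promoting protein Bim, rose by 1.32. Stress and immediate early genes had 1 higher and 2 lower of 14 by either adjustment (adjusted p = 0.0782), with Jun at -0.50, a call lost without either Tc17 STAT3-/- sample or Tc17 WT replicate 1 (adjusted p from 0.0846 to 0.137).

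CD8 T cell identity genes had 1 higher, Cd8a at 0.30, and 1 lower, Cd5 at -0.33, of 9 tested (the same counts over the list alone, camera adjusted p = 0.915), and the calls were weak (adjusted p = 0.0446 and 0.0371). That of Cd8a was lost without any 1 sample but Tc17 WT replicate 1 (adjusted p up to 0.253), and that of Cd5 without any but the Tc1 STAT3-/- samples (up to 0.255). Markers of other cells were mostly below the filter. Both tested B cell markers were higher in STAT3-/- Tc17 cells, Ighm by 1.77 and Cd79b by 0.78, and the 1 tested myeloid marker, Cd68, was lower by a log2 change of -1.12. Ighm changed by 0.52 with the mean of its probe sets. The 2 tested CD4 T cell markers (Cd4 at -0.24, Zbtb7b at 0.08) and the 1 tested NK and innate-like T cell marker (Sox13 at -0.12) were not called, and 0 of 6 erythroid markers passed the filter.

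**Figure D2:**
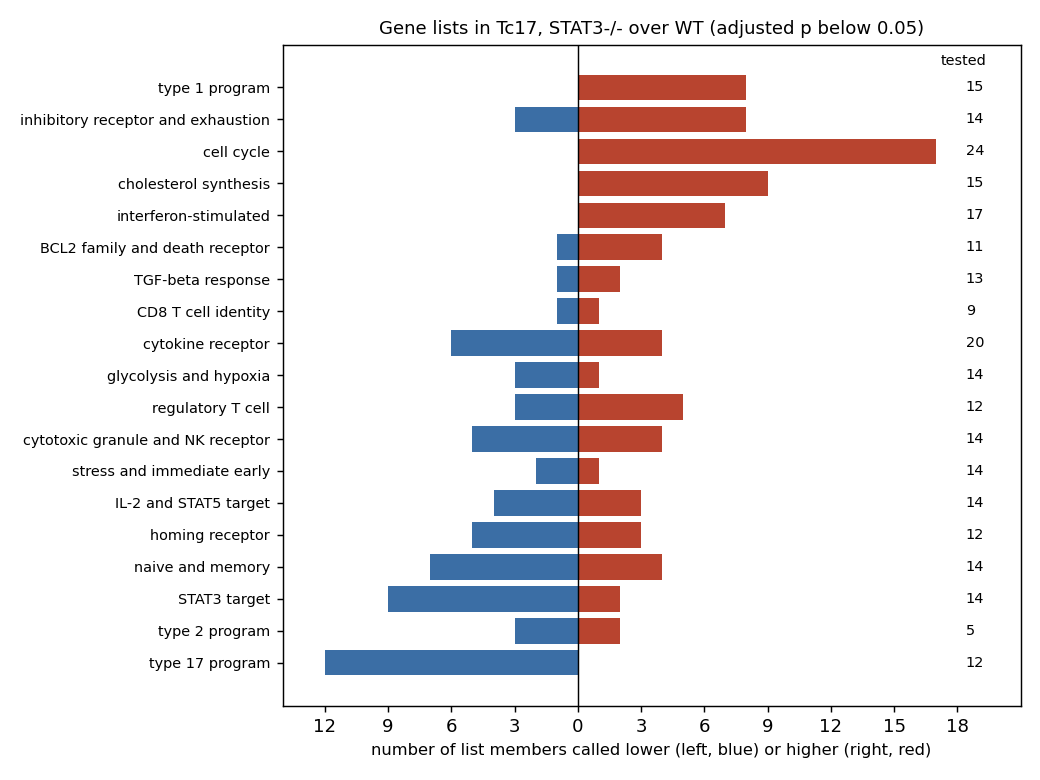
Number of tested members of each list called higher (right, red) or lower (left, blue) in STAT3-/- than in WT Tc17 cells, with the number tested at the right and lists ordered by their median change. The type 17 program had 12 of 12 lower and the cell-cycle list 17 of 24 higher, the latter falling to 7 under another scaling.

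The excess of higher genes in Tc17 depended on scaling. The median log2 change of all tested genes was 0.114, and 72.7% of calls were higher as deposited, against 49.2% (1071 higher, 1106 lower) after subtracting each array's median of tested genes, 54.8% (1139 and 938) after cyclic loess, 60.3% (1328 and 873) after quantile normalization and 82.5% (2266 and 481) after subtracting the median of all probes. Relative to all tested genes, the list medians were -1.71 for type 17, 0.52 for type 1, 0.29 for cell cycle and 0.25 for cholesterol synthesis. Camera compares the test statistics of a list, not its median change, with those of all other genes. The TGF-beta, cytokine receptor, glycolysis and CD8 identity lists leaned lower in it while their medians were above 0. Mean changes of the cytokine receptor (-0.05) and glycolysis (-0.03) lists were below 0. The regulatory T cell list leaned lower with a mean above 0. Camera's direction therefore need not be that of a list's median or mean change. The count of called genes was 1005 without Tc17 STAT3-/- replicate 1 and 943 without replicate 2.

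In Tc1 cells the same comparison called 6 genes. Besides Stat3, the lower genes were Ctse (-3.38 ± 0.10, adjusted p = 1.4e-06), Abhd17b, a depalmitoylating enzyme (-3.21 ± 0.16, adjusted p = 4.1e-05), and Nt5e, the ectoenzyme CD73 (-1.30 ± 0.15, adjusted p = 0.0220). The higher genes were Mid1 (3.36 ± 0.21, adjusted p = 0.00026) and Bckdhb, a subunit of the branched-chain keto acid dehydrogenase (1.08 ± 0.13, adjusted p = 0.0403). Nt5e and Bckdhb lie within 10 tested genes of each other in the genome. All 6 were called with the same sign in Tc17, and their interaction adjusted p-values ran from 0.325 to 0.672. Ifng (-0.16), Tbx21 (-0.01), Gzmb (-0.06), Il17a (0.10) and Il17f (-0.03) each had an adjusted p of 0.998.

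No list was called in Tc1, the lowest camera adjusted p being 0.0885 for inhibitory receptors, of which 0 of 14 members were called over all genes and 1 was higher adjusted over the list alone. The type 17 program had 0 of 12 members called and the STAT3 target list 0 of 14, or 1 lower adjusted over the list alone. Of all genes tested, 370 had an unadjusted p under 0.05. The count of called genes moved with the technical arrays, to 24 without them and 14 without that of Tc17 WT alone, and the calls of Nt5e and Bckdhb were lost without most single samples, at adjusted p-values up to 0.245 and 0.518, both without Tc1 WT replicate 1. Mid1 changed by 1.86 in Tc1 and 1.49 in Tc17 with the mean of its probe sets.

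The genotype effect differed between Tc17 and Tc1 for 676 genes, 442 with a more positive and 234 with a more negative change in Tc17. The Tc17 cytokine genes were among the most negative: Il17f differed by -4.40 ± 0.37, Il24 by -4.10 ± 0.16 and Il17a by -3.87 ± 0.32, with Cysltr1 (-3.50) and Ecm1 (-3.21). Il17f and Il17a were near background in every group but Tc17 WT, so the order of these differences is not established. Clnk (2.75), Xcl1 (2.58), Itih5 (2.58), Tmem273 (2.57) and Ifng (2.50 ± 0.15) led the positive side. Stat3 did not differ beyond the spread (-0.19, adjusted p = 0.672), and neither did Prf1 (-0.21, adjusted p = 0.493) or Eomes (0.66, adjusted p = 0.120), while Gzmb (0.99, adjusted p = 0.0038), Socs3 (-1.17, adjusted p = 0.0016) and Tbx21 (0.64, adjusted p = 0.0357) did. The Tbx21 call was lost without either sample of Tc1 WT, Tc1 STAT3-/- or Tc17 STAT3-/- (adjusted p from 0.0866 to 0.150).

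Of the lists, type 17 had 10 of 12 members more negative in Tc17 (12 adjusted over the list alone), with camera adjusted p = 4.2e-23 and adjusted p = 0.0080 with an estimated correlation. STAT3 targets had 7 of 14 (8 over the list alone), camera adjusted p = 7.1e-09 and adjusted p = 0.112 with an estimated correlation. Cell-cycle genes had 3 of 24 more positive (14 over the list alone), with adjusted p = 2.4e-05, or 0.162 as the adjusted p with an estimated correlation, and cholesterol genes 4 of 15 (8 over the list alone), with adjusted p = 0.00022, or 0.363 likewise. Camera also called homing receptors (adjusted p = 0.0072), naive and memory genes (0.0107), the type 1 program (0.0162), the type 2 program (0.0320) and cytokine receptors (0.0366), which with an estimated correlation had an adjusted p of 0.162, 0.438, 0.162, 0.207 and 0.495. With fry the naive and memory and cytokine receptor calls were lost (adjusted p = 0.106 and 0.217). In camera the former was also lost with no dim filter (adjusted p = 0.0647) and the latter without the technical arrays (0.0995). The homing call was lost without Tc17 WT replicate 2 (adjusted p = 0.0508), the type 1 call without replicate 1 (0.0546), and the type 2 call without either of these or Tc1 STAT3-/- replicate 2 (up to 0.0790). The cytokine receptor call was lost without any 1 sample but Tc1 WT replicate 1 and Tc17 STAT3-/- replicate 1 (up to 0.0817). As deposited 65.4% of the 676 genes were more positive, against 41.6% after subtracting the median of tested genes, 47.1% after cyclic loess, 53.2% after quantile normalization and 73.7% after subtracting the median of all probes. The count was 1555 without Tc17 WT replicate 1, 361 and 363 without Tc1 STAT3-/- replicates 1 and 2, 290 and 328 without those of Tc1 WT, and 250 and 244 without those of Tc17 STAT3-/-.

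Within WT cells, Tc17 differed from Tc1 in 2468 genes, 691 higher and 1777 lower. The cytokine genes Il24 (4.86 ± 0.11), Il17f (4.74 ± 0.26) and Il17a (4.17 ± 0.22) were among the genes furthest above Tc1, with Cysltr1 (4.15), the carboxypeptidase gene Cpd (4.13), Itgae, the integrin CD103 of tissue-resident T cells (4.05), the mucin gene Muc13 (3.91), Igfbp4 (3.90), the cytokine gene Lif (3.83) and Ecm1 (3.67). The Tc1 WT means of Il24 (4.27), Il17f (4.61) and Il17a (4.16) were near background, so the order of these differences is not established. Maf (3.36), Ifngr2 (3.21), Il21 (2.97), Foxp3 (2.02) and Socs3 (1.19) were higher too. Lower in Tc17 were Ly6c2 (-4.20), Havcr2 (-3.31), Ifng (-3.28 ± 0.11), Serpinb6b, a protease inhibitor (-3.12), Gbp7 (-3.00), Ms4a4b (-2.97), Itih5 (-2.54), Sytl2, a granule transport protein (-2.40), Ccl5 (-2.31) and Il18r1, an IL-18 receptor chain (-2.26). The killing genes Gzmb (-1.16) and Prf1 (-0.90) and the regulators Eomes (-1.58) and Tbx21 (-0.99) were lower as well. The cytotoxic list as a whole was split, with 7 higher and 7 lower of 14 by either adjustment, and camera did not call it (adjusted p = 0.736). Stat3 was 0.59 ± 0.18 higher (adjusted p = 0.0376), a call lost without any 1 sample of Tc1 WT, Tc17 WT or Tc17 STAT3-/- (adjusted p from 0.0610 to 0.165).

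The type 17 list had 12 of 12 tested members higher in WT Tc17 by either adjustment (camera adjusted p = 1.0e-18, and 0.0122 as the adjusted p with an estimated correlation). Here too Il17a and Il17f passed the dim filter only through Tc17 WT. STAT3 targets had 8 higher and 1 lower of 14 (9 and 3 adjusted over the list alone, camera adjusted p = 7.1e-07), and the cell-cycle list had 0 higher and 21 lower of 24 (24 lower over the list alone, camera adjusted p = 6.0e-08). The type 1 list had 8 lower of 15 (9 lower and 3 higher over the list alone, camera adjusted p = 0.0016). For these 3 lists the adjusted p was 0.0697 with an estimated correlation. TGF-beta response genes had 5 higher and 2 lower of 13 (6 and 2 over the list alone, camera adjusted p = 0.00065, and 0.279 as the adjusted p with an estimated correlation), led by Itgae, Ldlrad4 (2.18) and Pmepa1 (1.75), both inhibitors of TGF-beta signalling. Regulatory T cell genes had 7 higher and 2 lower of 12 (8 and 2 over the list alone, camera adjusted p = 0.00063, and 0.287 likewise), homing receptors 7 and 2 of 12 by either adjustment (0.00041, and 0.0697 likewise) and the type 2 program 4 and 1 of 5 by either adjustment (0.00021, and 0.0697 likewise). Naive and memory genes had 7 higher and 3 lower of 14 (8 and 3 over the list alone, 0.0193, and 0.402 likewise), cholesterol genes 7 lower of 15 (9 over the list alone, 0.0021, and 0.389 likewise) and interferon-stimulated genes 8 lower of 17 (10 lower and 1 higher over the list alone, 0.0250, and 0.405 likewise). The interferon call was lost without the Tc17 WT technical array (adjusted p = 0.0766), and the naive and memory call with no dim filter (0.140), with fry (0.221) and after subtracting the median of tested genes (0.0633). Of the B cell markers Ighm was lower at -1.35, or at -0.38 with the mean of its probe sets. Cell-cycle genes lower in Tc17 were 14, 13, 18 and 23 after median of tested genes, cyclic loess, quantile and median of all probes scaling. The median change of all genes was -0.10, and higher genes made up 28.0% of calls as deposited, against 50.8% (1142 higher, 1107 lower), 46.5% (985 and 1134), 39.8% (890 and 1348) and 18.3% (500 and 2233) under these, in that order. The count was 1100 without Tc1 WT replicate 1 and 1292 without replicate 2.

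Within STAT3-/- cells Tc17 differed from Tc1 in 204 genes, 104 higher and 100 lower. Itgae was 3.89 ± 0.20 higher, Foxp3 3.16 ± 0.22, Cpd 2.89, Tmem273 2.66 and Ldlrad4 2.46. Il18r1 was lower at -2.58, with Ly6c2 (-2.31), Havcr2 (-2.03), Serpinb6b (-1.92) and Plxnc1, a semaphorin receptor (-1.92). Il17a (0.30) and Il17f (0.34) did not pass the test (adjusted p = 0.735 for both), while Il24 was 0.76 higher (adjusted p = 0.0091) and Ifng lower at -0.78 (adjusted p = 0.0057). Prf1 (-1.11) and Eomes (-0.92) were lower, and Gzmb (-0.17) and Tbx21 (-0.35) were not called. The Ifng and Eomes calls were lost without Tc1 STAT3-/- replicate 1 or either Tc17 STAT3-/- sample (adjusted p up to 0.0747 and 0.219), and the Il24 call without Tc1 STAT3-/- replicate 1 or Tc17 STAT3-/- replicate 2 (0.0854 and 0.105).

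TGF-beta response genes had 5 of 13 members higher and 0 lower (6 and 1 adjusted over the list alone), including Pmepa1 (1.44) and Nt5e (1.29), with camera adjusted p = 1.9e-08 and adjusted p = 0.156 with an estimated correlation. Regulatory T cell genes had 4 of 12 higher (7 higher and 1 lower over the list alone, camera adjusted p = 1.2e-06, and 0.263 as the adjusted p with an estimated correlation), and the type 2 program 2 of 5 (4 over the list alone, 2.6e-06, and 0.126 likewise). The type 1 program had 1 higher and 5 lower of 15 (3 and 7 over the list alone, 0.0019, and 0.156 likewise) and cytotoxic genes 1 higher and 3 lower of 14 (3 and 5 over the list alone, 0.0103, and 0.304 likewise). The cell-cycle list was called lower with 0 of 24 members called (0.0016, and 0.304 likewise). The type 1, cytotoxic and cell-cycle calls were lost without Tc1 STAT3-/- replicate 2 (adjusted p = 0.0595, 0.0595 and 0.0919), and the cytotoxic call also without Tc17 STAT3-/- replicate 1 (0.0509). Of the type 17 list 2 of 12 members were higher, Il24 and Ahr, a ligand-activated transcription factor (1.33), with 2 higher and 3 lower adjusted over the list alone, and camera did not call it (adjusted p = 0.462). The Ahr call was lost without Tc17 STAT3-/- replicate 2 (adjusted p = 0.0523). The B cell marker Cd79b was 0.81 higher, a call lost without Tc1 STAT3-/- replicate 2 or either Tc17 STAT3-/- sample (adjusted p up to 0.0811), and the myeloid marker Cd68 lower at -0.98. The count was 99 and 122 without Tc1 STAT3-/- replicates 1 and 2, and 90 and 65 without those of Tc17 STAT3-/-.

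Of the 2468 genes that differed between WT Tc17 and WT Tc1, 1735 (70.3%) differed the opposite way between STAT3-/- and WT Tc17 cells, a share that was 42.6% (796 of 1868) without Tc17 STAT3-/- replicate 1 and 41.6% (778 of 1868) without replicate 2. Of the 691 genes higher in WT Tc17, 470 (68.0%) were lower in STAT3-/- Tc17, where independent lists of these sizes would share 47.2. Of the 1777 lower genes, 1265 (71.2%) were higher in STAT3-/- Tc17, against 324 for independent lists, and 14 genes were called in both with the same sign. Both comparisons use the Tc17 WT samples. In 100 simulations of unchanged groups against them the mean overlap was 0 in both directions, but only 0.24 genes were called on average, so this sets no level for the overlaps. Across genes, which are not independent replicates, the changes correlated at r = -0.84 with covariance -0.144, against -0.50 and -0.0076 in the simulations. With 1 Tc17 WT sample in each comparison, so that none was shared, the higher-to-lower overlap was 342 or 325 by which sample went where (41.0 and 42.2 for independent lists) and the lower-to-higher overlap 853 or 821 (299 and 308). The covariance was then -0.131 or -0.128 and r = -0.71 or -0.69. After subtracting the median of tested genes the higher-to-lower overlap was 800 of 1142 genes (70.1%). The lower-to-higher overlap was 764 of 1134 genes (67.4%) after cyclic loess and 735 of 1107 (66.4%) after subtracting the median of tested genes. It was 2034 and 818 without Tc17 WT replicates 1 and 2, 597 and 724 without those of Tc1 WT, and 532 and 515 without those of Tc17 STAT3-/-, and the other overlap was 279 without Tc1 WT replicate 2 and 264 and 263 without the Tc17 STAT3-/- replicates.

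Comparing Tc17 over Tc1 between genotypes uses no sample on both sides. Cells of both genotypes were cultured together, however, so differences between cultures can still enter both sides. Over the genes called in WT, the change in STAT3-/- cells had a slope of 0.22 on the change in WT and correlated at r = 0.51 across genes, and choosing genes by their WT change draws such a slope toward 0. Genes higher in Tc17 in both genotypes numbered 56 (7.29 for independent lists) and genes lower in both 64 (18.0 for independent lists). Itgae was among the genes with nearly equal changes, with 4.05 in WT and 3.89 in STAT3-/-, and Il17f among those far from equal, with 4.74 and 0.34.

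**Figure D3:**
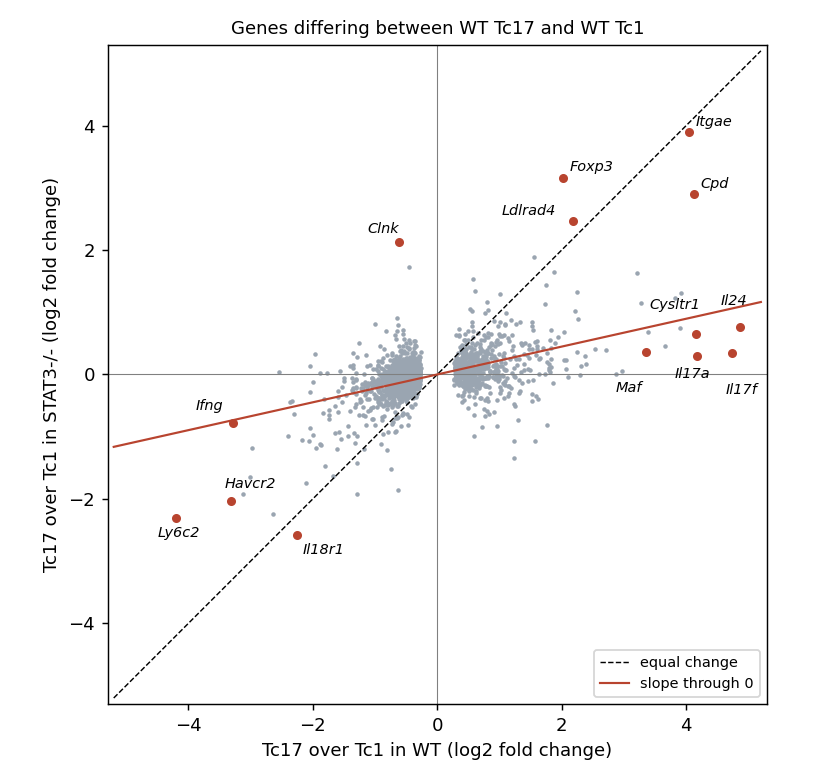
Log2 fold change of Tc17 over Tc1 in WT (x axis) and in STAT3-/- cells (y axis) for the 2468 genes called in WT, each point 1 gene, with a dashed line of equal change and a red line at the slope of 0.22. Itgae and Ldlrad4 lie near the dashed line, while Il17a (0.30), Il17f (0.34), Maf (0.36) and Il24 (0.76, the 1 of these 4 that was called in STAT3-/-) lie far below it.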

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

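No test in this part was chosen after its result was seen. The effect of STAT3 loss differed between Tc17 and Tc1 cells for 676 genes by limma's interaction test (2379 at an unadjusted p under 0.05), and each value below is the change in Tc17 minus the change in Tc1 on the log2 scale. Genes of the type 17 program and others lost with it were more negative in Tc17: Il17f (-4.40), Il24 (-4.10), Il17a (-3.87), Cysltr1 (-3.50), Ecm1 (-3.21), Igfbp4 (-3.15), Maf (-3.00), Il21 (-2.92), Tgm2 (-2.70), Anxa3 (-2.33) and Hif1a (-0.93, or -0.49 and uncalled at adjusted p = 0.197 with the mean of its probe sets). Receptors followed, with Il6ra (-1.89), Ifngr2 (-1.58), Klrc1 (-1.46), Cxcr6 (-1.43), S1pr1 (-1.42), Ccr4 (-1.35) and Klrd1 (-1.17), as did Satb1 (-1.56), the STAT3 targets Socs3 (-1.17) and Bcl3 (-0.93), and the myeloid marker Cd68 (-1.09).

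Genes more positive in Tc17 included effector genes, namely Xcl1 (2.58), Ifng (2.50), Ly6c2 (1.89), Fasl (1.80), Ccl5 (1.67), Gzmb (0.99), Nkg7 (0.98) and Tbx21 (0.64), and the inhibitory receptor genes Cd244a (1.52), Havcr2 (1.28) and Pdcd1 (0.76) with Prdm1 (1.33). Interferon-inducible genes were Mndal (2.31), Gbp3 (1.22) and Gbp5 (1.08). Others were Clnk (2.75), Itih5 (2.58), Tmem273 (2.57), Pygm (2.18), Bcl2l11 (1.02), Ikzf2 (0.96), Lrrc32 (0.89), the cholesterol genes Dhcr7 (0.93) and Hmgcs1 (0.61), the replication genes Mcm5 (0.78) and Mcm3 (0.56), and the B cell markers Ighm (1.70, or 0.46 and uncalled at adjusted p = 0.0624 with the mean of its probe sets) and Cd79b (0.74). The calls of Bcl2l11, Cd79b, Dhcr7, Hmgcs1, Gbp5, Ikzf2, Lrrc32, Mcm3, Mcm5, Nkg7 and Tbx21 here, and of Klrd1 above, were lost when at least 1 of the samples was left out, for Lrrc32 and Nkg7 only Tc17 STAT3-/- replicate 2 (adjusted p = 0.0540 and 0.0536) and for the others up to 0.156 (Mcm3, without Tc17 STAT3-/- replicate 1).

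Median differences of the lists called in the interaction were -1.60 for type 17, -0.53 for type 2, -0.49 for STAT3 targets, -0.41 for homing receptors, -0.27 for naive and memory genes, -0.0064 for cytokine receptors, 0.40 for cell cycle, 0.42 for cholesterol synthesis and 0.64 for type 1. Of these, type 17 kept its call with an estimated correlation. Camera did not call the interferon-stimulated (adjusted p = 0.0516), inhibitory receptor (0.126) or cytotoxic (0.233) lists in the interaction. The cytotoxic list had 2 members more positive and 3 more negative of 14 (4 and 4 adjusted over the list alone).

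Among 3877 tested probe sets with no gene symbol, 482 differed between the genotypes in Tc17, 277 higher and 205 lower in STAT3-/- cells, and 0 of these probe sets differed in Tc1. They belong to no named gene here. Of 759 probe sets with several symbols, 110 differed in Tc17.

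Each pairwise comparison holds 4 samples, which allow 3 splits, so the share of splits with as many genes cannot go under 0.05. In each comparison 1 of 3 splits, the real one, gave as many genes. The real counts were 2473 for the genotypes in Tc17, 6 in Tc1, 2468 for Tc17 over Tc1 in WT and 204 in STAT3-/-, and the highest of the other splits gave 0 each time.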

How the results depend on the processing

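The settings chosen after seeing the data were leaving out the Tc17 WT technical array, subtracting each array's median of tested genes, averaging the biological arrays of a group as 1 sample, and splitting the Tc17 WT samples for the overlaps. Changes of named genes kept their direction and side of the threshold in 8021 comparisons with other settings, lost their call in 472, gained one in 60 and turned in 0, and list tests did so in 1325, 69, 30 and 1. The turned list was the cytotoxic granule and NK receptor list in WT Tc17 over Tc1. Fry called it lower (median -0.22, fry adjusted p = 0.0265), where camera leaned higher without a call. Fry does not compare a list with other genes, while camera compares its test statistics with theirs. The list median lay below the -0.10 of all tested genes, so the median change does not account for camera's direction. Leaving out 1 sample leaves a group with a lone sample, assumed to vary like the other groups. This gave 943 to 3191 genes for STAT3-/- over WT in Tc17, 4 to 7 in Tc1, 244 to 1555 for the interaction, 1100 to 3232 for Tc17 over Tc1 in WT and 65 to 247 in STAT3-/-, 263 to 457 for the overlap of genes higher in WT Tc17 and lower without STAT3, 515 to 2034 for the opposite overlap, and 0.19 to 0.24 for the slope.

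Without the technical arrays the counts were 24 in Tc1, 1259 for the interaction and 409 for Tc17 over Tc1 in STAT3-/-. Leaving out the Tc17 WT technical array alone gave 14 in Tc1, pairing technical arrays with replicate 1 gave 16 there, and 12 separate arrays gave 13. Averaging the biological arrays as 1 sample gave 932 in Tc17, 117 for the interaction, 946 for Tc17 over Tc1 in WT and 52 in STAT3-/-. The cause was not tested. With all arrays and the sample as a random block the counts were 6274, 266 in Tc1, 4796 for the interaction, 6101 and 1592. The estimated correlation of arrays of 1 sample was then -0.73, and such a value shrinks the error of a sample's mean. Arrays averaged as 1 sample were less alike than biological arrays 1 and 2 of a group. The technical array stood apart from both, with SDs of the differences of 0.209 to 0.352 from array 2 and 0.195 to 0.372 from array 1.

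The replicate numbers were not shown to pair samples, and the labels do not say whether a number marks a shared culture of both genotypes. Deviations from group means of same-numbered samples correlated at 0.46 for the Tc1 genotypes and 0.098 to 0.160 for other pairs of groups, and at 0.172 and 0.00036 to 0.0794 with biological arrays alone. With the number as a block, 15 genes were called in Tc1 and 1018 for the interaction, and with a block within Tc type 31 and 1150.

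Stricter thresholds lower counts by construction. At an adjusted p under 0.01, 1099 genes were called in Tc17, 216 for the interaction, 1113 for Tc17 over Tc1 in WT and 108 in STAT3-/-. With at least 1.5-fold change the counts were 909 in Tc17, 920 for Tc17 over Tc1 in WT, and 237 and 365 for the overlaps. Testing more features, the interaction had 384 genes with no dim filter and 371 probe sets when every one was tested, Tc17 over Tc1 in STAT3-/- had 128 of the latter, and the lower-to-higher overlap was 766 with no dim filter. That overlap was 764 of 1134 genes (67.4%) after cyclic loess and 735 of 1107 (66.4%) after subtracting the median of tested genes. The latter scaling gave 800 of 1142 (70.1%) for the other overlap. These counts moved with the number of genes called, while under these scalings the shares stayed near the 71.2% and 68.0% found as deposited. With no dim filter the shares were 65.9% for the lower-to-higher overlap and 62.4% for the other. With at least 1.5-fold change they were 63.1% and 69.3%. Leaving out single samples moved the shares further. With the Tc17 WT samples split the lower-to-higher overlap was 821 for replicate 2 against Tc1, with fewer samples in each comparison. Only the groups compared in the fit gave 1479 genes for Tc17 over Tc1 in WT, with fewer samples behind the spread. Signal over background limits what could be tested: 12318 genes lay below the filter, Il23r among them.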

Other observations

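The neighbour count in Tc1, the tests on the technical array and those on the excess of higher genes were chosen after the results were seen, as were the genes of the next paragraph that the naming rule does not cover.

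Between Tc17 and Tc1, 25 genes were called in both genotypes with opposite sign. The lists held 691 higher and 1777 lower genes in WT, and 104 higher and 100 lower in STAT3-/-, of 9862 tested. Independent lists of these sizes would share about as many with opposite sign, so the count shows no excess of reversals. Satb1 was higher in Tc17 in WT (0.72) and lower in STAT3-/- (-0.85), and Fosl2, a subunit of the AP-1 transcription factor, changed by 0.91 and -0.61. Emp1, an epithelial membrane protein, changed by 1.23 and -1.35. Dapl1 went the other way (-0.68 and 0.63), as did Clnk (-0.62 and 2.13) and Tph1, a tryptophan hydroxylase that makes serotonin (-0.45 and 1.73). With any 1 sample left out Satb1 and Emp1 were called both times. The Fosl2 call in STAT3-/- was lost without any 1 of the 4 STAT3-/- samples (adjusted p from 0.0561 to 0.113) and that of Dapl1 without Tc1 STAT3-/- replicate 2 or either Tc17 STAT3-/- sample (0.101 to 0.157). In WT the Clnk call was lost without Tc1 WT replicate 2 (0.0643) and that of Tph1 without the latter (0.135) or Tc17 WT replicate 1 (0.0585), and Emp1 changed by 0.74 and -0.69 with the mean of its probe sets.

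Some of the genes with the smallest p between genotypes in Tc1 sat beside each other in the genome, such as Nt5e by Bckdhb, Abhd17b by Cemip2, and Atp10d by Txk, while Ctse, with the smallest p of all, had no such neighbour. Of these, Cemip2 and Atp10d (limma adjusted p = 0.103 each) and Txk (0.657) were not called. Only 6 genes, Stat3 among them, were called in Tc1, so most of the top 50 were not. Of the top 50 without Stat3, 22 had another within 10 tested genes, against a median of 4 and a 95th percentile of 10 in 10000 random sets (permutation p = 1e-04, the smallest these can give), and 26 within 20 tested genes, against a 95th percentile of 15. Neighbours changing together in any comparison is argued against, since the top 50 of Tc17 over Tc1 had 2 in STAT3-/- (5 within 20) and 8 in WT (11 within 20). The top 50 of STAT3-/- over WT in Tc17 and of the interaction each had 13 (permutation p = 0.0068, and 15 within 20, p = 0.0622), and DNA with the same effect in both cell types would cancel in the interaction. A candidate explanation is DNA of another mouse strain carried along in 1 of the mouse lines, which were told apart by allelic markers, while an effect of STAT3 loss on these genes stays open and was not tested.

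The Tc17 WT technical array differed most from its biological partner. A compressed signal range on that array is argued against as the whole cause, since after cyclic loess the SD of the differences stayed at 0.346, against at most 0.289 in the other groups. Il17a and Il17f lay 1.46 and 1.65 above the biological arrays of the group and Il23r at -1.75 from them. Further Tc17 differentiation of the cells on it could not be decided, since after cyclic loess genes higher in Tc17 than Tc1 had a median deviation of -0.0369 and genes lower -0.0475, with a slope of 0.0539 ± 0.0153 on the Tc17 over Tc1 change.

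The excess of higher genes in STAT3-/- Tc17 (72.7% of calls) was not due to that array alone, as 66.6% were higher without it. A narrower signal range on the Tc17 WT arrays and a broad rise of expressed genes without STAT3 cannot be told apart. The 12318 genes below the dim filter had a median change of -0.0658 ± 0.0015 (bootstrap SE), opposite to the 0.114 of tested genes, but normalization to a common level sets such a balance under either. That median was -0.0461 without technical arrays and -0.0023 between the genotypes in Tc1.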
